A study of Drosophila melanogaster with 2 samples.

How the data were processed

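Chromatin immunoprecipitation with sequencing (ChIP-seq) was done on whole embryos of transgenic flies that express CG10366 fused to eGFP. Per the labels, the precipitation used an antibody against GFP, chromatin was fragmented by sonication to 200 to 800 bp, embryos were 0 to 24 h old, and the 2 libraries are biological replicates 1 and 2 aligned to dm6. The aligner, the peak caller and their versions are not given in the sources used here. Reads, signal tracks and control libraries were not analysed here.

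For each library, and for both together, the authors deposited a ranked list of candidate peaks and a thresholded list. The lists are per sample for the replicates, and the series-wide and conservative lists rest on both libraries. The deposited lists give each peak's position, summit and signal, which is the authors' own value per peak and was used only to rank, describe or filter peaks within a list. They also give a score, which in the deposited thresholded lists began at 830 of at most 1000. The −log10 of the global IDR stands in the deposited ranked lists, and the thresholded lists were found to be the ranked peaks with a value of at least 2, that is an IDR of 0.01 or less. A small number of ranked peaks met that value but were left out of the thresholded lists, 148 in the series-wide case. Per the file descriptions, the thresholded lists were derived from 1 more file than the ranked ones, whose content was not used here. That it served to exclude regions was inferred from these differences. That the 2 signals held for each peak of the conservative ranked list are those of the 2 libraries was likewise inferred, from their values, and the rank comparison of the replicates rests on it. Read totals are not part of the lists, so depth and its effect on each replicate's list remain unknown.

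Passing peaks were those in the series-wide thresholded list, and failing candidates were ranked peaks above that IDR. The series-wide list held 2 repeated intervals, which were kept as deposited since their summits differ. Genes, start sites and exons came from Ensembl release 115 for the same assembly, without transposable elements, and sequence came from the RefSeq copy of that assembly, whose arm names and lengths fit the peak coordinates. Coordinates are given 1-based. A promoter peak had its summit within 500 bp of a start site of any annotated transcript. Each summit was placed in the first matching class of coding exon, 5' UTR, 3' UTR, non-coding exon, intron and intergenic.

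Shares were compared by Fisher's exact test, two-sided, with passing peaks against failing candidates. Log2 odds ratios had 0.5 added to each cell, and ± gives their standard error. Values of p under 1e-300 were not told apart. Benjamini-Hochberg adjustment was made over the 6 arms, the 6 feature classes, the 19 gene lists, the 17 motifs or the 20 chosen 8-mers, with a threshold of 0.05. Gene lists were compared with other protein-coding genes that had a ranked candidate within 500 bp of a start site, 5950 genes in all with the lists included. Replicate lists were compared by overlap of at least 1 bp and by 1000 circular shifts within each arm, one-sided. Motif windows were 100 bp and 8-mer windows 50 bp to either side of the summit, and failing windows were matched in bins of 5 percentage points of GC content and on promoter position. Matching kept 4904 of 5140 passing windows for motifs and 4778 for 8-mers; the rest, mostly with GC content that too few failing windows had, were left out.

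The gene lists, motifs, tests, and the rule for named genes were fixed before the data were examined. The rule took the genes within 500 bp of the 25 strongest summits, up to 4 members of each list with the highest signal, and CG10366; a summit with no start site in reach was named by the gene around it or by the nearest start site. Feature classes, positions relative to start sites, the comparison of the top 500 peaks, types of small RNA gene, GC profiles, 1 gene drawn of each divergent pair and 1 Mb windows were added after seeing the data. Flanks were planned as 300 to 500 bp from the summit; a first look used 300 to 400 bp on both sides, and the side at lower coordinates was settled on after it. No test compares groups of samples, since there is 1 group of 2 libraries.

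The tests were run on simulated data only after the real lists had been analysed. A seeded list of 75 genes with 4-fold raised odds was called in 20 of 20 runs of the gene list test, over 3814 genes, and 2 of 80 unseeded lists were called beside it. With no list seeded, 3 of 80 were called. Of the real lists, only cytoplasmic ribosomal proteins had 75 genes with a candidate, and the next largest had 44. The seeded runs therefore do not show how often a raised smaller list would be missed. A CTCF core sequence planted in 2% of windows was called in 20 of 20 runs over 9000 windows, with 2 of 320 other motifs called beside it, and a planted 8-mer in 5 of 5. With nothing planted, 0 of 320 motif tests and 0 of 100 8-mer tests passed. Both sides of these motif and 8-mer simulations were drawn from the same failing windows, without matching. They do not show how often false calls arise where GC content differs, as it did between real passing and failing windows. In the overlap test the first unrelated list came out below 0.05, so 20 were run, and 3 of 20 did so, with a mean overlap of 2.35% against a shifted mean of 2.35%. So few runs leave open whether this test calls unrelated lists too often.

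Alternatives were the conservative list, each replicate's own list, windows of 250 and 1000 bp, other backgrounds, arms only, other overlap rules, and an IDR of 0.001. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.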

Results

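Binding of CG10366 was mapped in whole Drosophila melanogaster embryos collected 0 to 24 h after laying. The flies carried CG10366 fused to eGFP, and chromatin was immunoprecipitated with an antibody against GFP. The 2 libraries, replicate 1 and replicate 2, are biological replicates by their labels and form 1 group, so the comparisons below are between places in the genome and between the replicates' lists. Each library had its own peak list, and 2 further lists were made from both libraries. The lists hold no read totals, so sequencing depth is unknown here. Intervals on shares are 95% Wilson intervals and cover counting error only.

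In the series-wide list, 5153 peaks passed the authors' irreproducible discovery rate (IDR, the expected share of peaks that do not repeat) threshold, and 28717 ranked candidates failed it. The passing peaks had a median width of 330 bp and covered 1439387 bp of the dm6 genome. The authors' signal value of a peak ranged from 2.01 to 3230 with a median of 142, so the strongest peak stood 22.8-fold above the median. The conservative list held 4989 peaks. Replicate 1 alone gave 4876 peaks and replicate 2 alone gave 3378. Of the series-wide peaks, 5140 lay on the arms 2L, 2R, 3L, 3R, 4 and X, and 13 lay on unplaced X scaffolds.

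The replicates shared most of their strong sites. Of the 3378 replicate 2 peaks, 2912 overlapped a replicate 1 peak by at least 1 bp (86.2%, 85.0 to 87.3%). In the other direction, 2969 of 4876 replicate 1 peaks were met (60.9%, 59.5 to 62.3%). Moving the replicate 2 list along each arm left a mean overlap of 1.91% and at most 2.67% over 1000 circular shifts (one-sided permutation test, p = 0.001, the smallest these shifts can give). Of the series-wide peaks, 2985 overlapped peaks of both replicates (57.9%), 1401 of replicate 1 alone (27.2%), 333 of replicate 2 alone (6.46%) and 434 of neither (8.42%). Median signal was 211 for peaks found in both replicates and 83.4 for peaks found in neither. Across the 4989 conservative peaks, signals of the 2 libraries ranked alike (Spearman's rho = 0.804 across peaks, which are not independent replicates). The IDR selects peaks with similar ranks in both, which raises this rho, and over all 66223 ranked candidates it was 0.360.

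CG10366 peaks lay at promoters far more often than failing candidates did. A start site was within 500 bp of 2311 of the 5153 passing summits (44.8%, 43.5 to 46.2%), against 5444 of 28717 failing ones (18.96%, log2 odds ratio 1.80 ± 0.05 SE, two-sided Fisher's exact test, p < 1e-300). Random positions on the same arms were near a start site in 13.7% of draws. The promoter share was highest among the strongest peaks: 63.8% of the top 500 by signal (59.5 to 67.9%) and 42.8% of the remaining 4653 (two-sided Fisher's exact test, p = 3.80e-19). These promoter summits marked 2715 of 13986 protein-coding genes (19.4%, 18.8 to 20.1%).

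**Figure D1:**
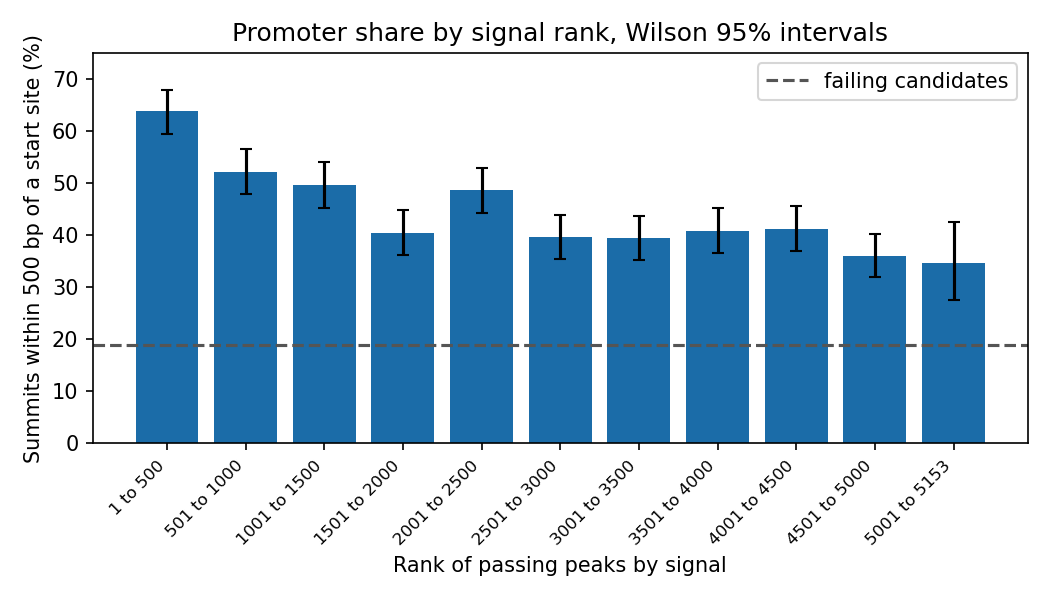
Share of passing summits within 500 bp of a start site (vertical axis, %) in bins of peaks ranked by signal (horizontal axis), with 95% Wilson intervals; the dashed line is the share among failing candidates. The share was 63.8% in the top 500 peaks and 36.0% at ranks 4501 to 5000, against 18.96% for failing candidates.

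Promoter summits sat just upstream of the start site. Of 2186 summits within 500 bp of a protein-coding start site, 1805 lay upstream of it (82.6%, 80.9 to 84.1%), against 2441 of 4714 failing summits (51.8%; two-sided Fisher's exact test, p = 9.71e-142). The median passing position was -99 bp, with quartiles of -182 and -35 bp. The fullest bin, 50 to 100 bp upstream, held 456 summits. Failing summits had a median position of -9 bp and were spread over both sides.

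**Figure D2:**
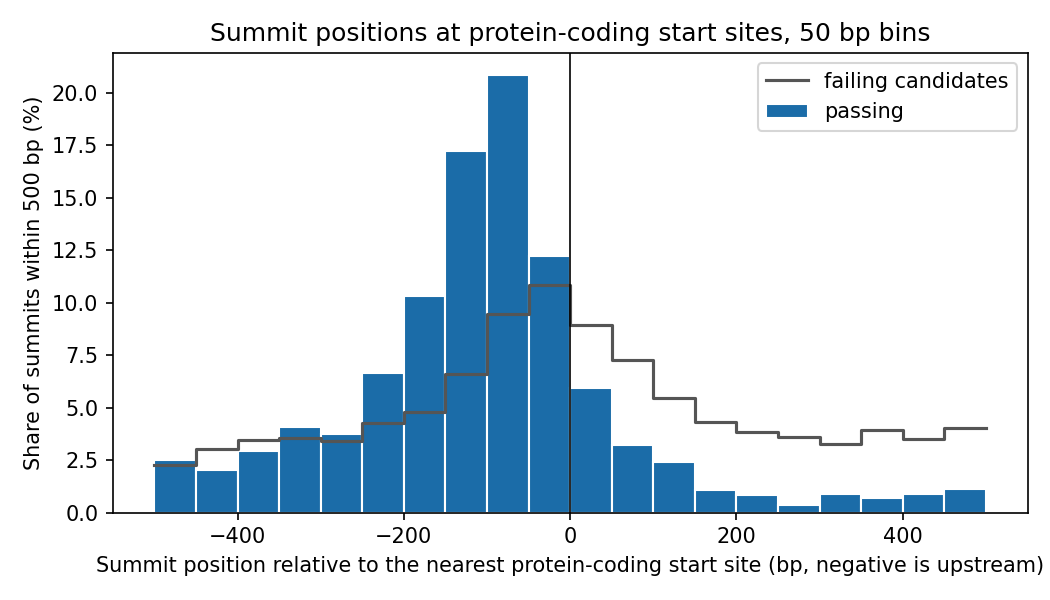
Position of summits relative to the nearest protein-coding start site (horizontal axis, bp, negative is upstream) as a share of the summits within 500 bp (vertical axis, %), in 50 bp bins; bars are the 2186 passing summits and the line the 4714 failing ones. Passing summits gather upstream, with 20.9% between 100 and 50 bp upstream, against 9.48% of failing summits.

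Peaks were nearly absent from coding sequence. Coding exons held 45 of the 5153 passing summits (0.873%, 0.653 to 1.17%), against 5102 of 28717 failing summits (17.8%, log2 odds ratio -4.60 ± 0.22 SE, two-sided Fisher's exact test, adjusted p < 1e-300 over 6 features). Introns held 2516 passing summits (48.8% against 42.3%, exact test, adjusted p = 6.95e-18) and intergenic sequence 1995 (38.7% against 30.4%, adjusted p = 8.53e-31). Coding exons were also avoided away from promoters: among summits over 500 bp from any start site, 26 of 2842 passing ones (0.915%) and 17.97% of failing ones were in coding sequence. Introns held 68.6% of those distal passing summits (66.9 to 70.3%), against 47.3% of failing ones (exact test, adjusted p = 5.65e-104).

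The 25 strongest peaks carried signals of 1651 to 3230, and each overlapped a peak in the conservative list and in both replicates. A start site was within 500 bp of 18 of them. The strongest peak (3L, 19590455 to 19590776, signal 3230) lay in intergenic sequence 93 bp upstream of CG14100, and its summit sequence was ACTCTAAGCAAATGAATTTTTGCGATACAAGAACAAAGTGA. The next (2L, 6612546 to 6612888, signal 3135) lay in an intron of CG11050, with the summit sequence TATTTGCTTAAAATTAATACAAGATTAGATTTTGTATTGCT. The third (X, 2703720 to 2704056, signal 3022) lay 35 bp upstream of Ugalt, a UDP-galactose transporter gene. The X also carried a peak in an intron of ph-p, a Polycomb group gene (2137196 to 2137535, signal 2492), and one in an intron of CG32772 (4910208 to 4910528, signal 1950).

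Members of the mitochondrial ribosomal protein list stood near 4 of these top peaks. A peak 130 bp upstream of mRpL41 (2R, 15217584 to 15217922) had a signal of 2806, and lncRNA:CR44463 started within 500 bp of it. The shared promoter of mRpS10 and the methyltransferase gene Art3 (3R, 15229367 to 15229699) had 2162. The peak at CenG1A, 392 bp upstream of mRpS23 (2L, 13835312 to 13835612), had 2192. The peak 80 bp past the start site of mRpL23 and 130 bp upstream of CG9004 (3L, 2373453 to 2373753) had 1756. Apart from that list, a peak of 2228 lay 85 bp upstream of the nearest start site of PNPase, a polynucleotide phosphorylase gene (3R, 31404503 to 31404812). Its summit fell in the 5' UTR class, which does not say whose 5' UTR it is. The CG7601 and CIA30 pair had a peak of 1887 (3R, 29736689 to 29736997).

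The remaining top peaks were described one by one and not tested as a set. Chro, which encodes the chromodomain protein Chromator, and Ssl1, which encodes a TFIIH subunit, shared a peak of 2066 (3L, 22878712 to 22879058). HmgD, a high mobility group gene, held one of 2033 in an intron (2R, 21703155 to 21703656), and the transcription factor gene Adf1 held one of 1791 in an intron (2R, 6662886 to 6663222). The peak at eIF6 and asRNA:CR45928 had 2025 (2R, 23850255 to 23850556). Other promoter peaks stood at Tcs5 and CHMP2B (signal 2298), CG18549 (1921), CG5611 and Mtl (1912), px (1822), CG9147 and Fbw5 (1790), gish (1699), CG1888 (1664) and CG8320 and Pex11ab (1651). Away from promoters, a peak of 2053 lay 11913 bp from CG13323, and one of 1675 lay 903 bp from lncRNA:CR45643.

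Promoters of head-to-head gene pairs were preferred. Of 5052 protein-coding genes with a divergent partner starting within 1000 bp, 1752 had a summit within 500 bp (34.7%, 33.4 to 36.0%), against 963 of 8893 other genes (10.8%; log2 odds ratio 2.13 ± 0.07 SE; two-sided Fisher's exact test, p = 5.13e-247). The pairs Tcs5 and CHMP2B, Art3 and mRpS10, and CG7601 and CIA30 named above each shared a single summit upstream of both genes. Genes of a pair share summits, so they are not independent; with 1 gene drawn from each pair or chain of pairs, a test added after seeing the data, 834 of 2412 had a summit (34.6%, log2 odds ratio 2.12 ± 0.08 SE).

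Ribosomal protein genes were the clearest gene group. Of 75 cytoplasmic ribosomal protein genes with a ranked candidate at a start site, 65 had a passing summit (86.7%, 77.2 to 92.6%), against 45.1% of 5875 other such genes (log2 odds ratio 2.92 ± 0.48 SE; two-sided Fisher's exact test, p = 1.93e-13, adjusted p = 3.67e-12 over 19 lists). The strongest were at RpS27 (signal 685), RpL7 (634), RpL41 (527) and RpL34b (515). Mitochondrial ribosomal protein genes were also marked more often, 28 of 42 (66.7% against 45.5%, exact test, adjusted p = 0.0362), led by mRpL41, mRpS23, mRpS10 and mRpL23. That second call was lost without replicate 1, in the list of replicate 2 alone (30.8% against 28.8%, exact test, adjusted p = 1), and also with windows of 250 bp and 1000 bp, in the conservative list and at an IDR of 0.001.

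Receptor, epidermal and neuronal genes were marked less often. None of 15 odorant and gustatory receptor genes with a candidate had a passing summit (0%, up to 20.4%, against 45.7% of other genes; Fisher's exact test, adjusted p = 0.00108), nor had any of 9 epidermis and cuticle genes (0%, up to 29.9%; Fisher's exact test, adjusted p = 0.0316). Of 16 neuronal genes, 2 had one (12.5%; Fisher's exact test, adjusted p = 0.0368): elav, the pan-neuronal RNA-binding protein gene (signal 762), and scrt (77.4). Without replicate 1, that is in the list of replicate 2 alone, the epidermal call (exact test, adjusted p = 0.0990) and the neuronal call (adjusted p = 0.107) were lost, and each was lost in 3 further settings. With a window of 250 bp the receptor call was lost (exact test, adjusted p = 0.0684).

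The other 14 lists did not pass the test after adjustment. Insulator and promoter-binding protein genes had 13 of 18 (72.2%; Fisher's exact test, p = 0.0311, adjusted p = 0.0843), with Chro, Cp190 (signal 545), Trl (476) and row (330) highest. This list passed in 5 of 9 other settings, among them the conservative list (exact test, adjusted p = 0.00591) and in replicate 1's list alone (adjusted p = 0.00458). Heat shock genes had 7 of 10, led by Hsp27 (818), Hsp26 (350), Hsp83 (318) and Hsc70-4 (227). General transcription genes had 14 of 22, led by Taf5 (531), TH1 (444), Polr2B (429) and TfIIA-L (408). Polycomb and Trithorax group genes had 10 of 17, led by brm (1287), ph-p (800), E(z) (507) and Su(z)12 (294). Cell cycle and DNA replication genes had 15 of 31, with Dp (516), RnrS (300), dpa (278) and Mcm2 (215). Germline and maternal genes had 8 of 14, with bgcn (343), egl (262), piwi (216) and plu (182).

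Among developmental and metabolic lists, segmentation genes had 3 of 16, nkd (404), bcd (228) and cad (114), with an adjusted p of 0.0992 by the exact test. Mesoderm and muscle genes had 7 of 19, with Msp300 (555), tin (549), sls (412) and mbc (324). Gut, fat body and haemocyte genes had 3 of 7, fkh (149), ush (91.5) and peb (86.7). Hox genes had 0 of 4 and histone genes 0 of 2, both too few to test well, and histone gene copies are near-identical. Against all protein-coding genes in place of those with a candidate, histone genes were lower (0% against 19.6%, exact test, adjusted p = 1.90e-10), and cell cycle (0.0357) and general transcription genes (0.0255) were higher. Only 2 of the 113 histone genes had a ranked candidate. The rest could not hold a passing summit, so the low histone share was largely set before this test. In replicate 1's list, gut, fat body and haemocyte genes were lower (exact test, adjusted p = 0.0342). Respiratory chain genes had 19 of 44, with ND-ASHI (581), ND-MWFE (440), ND-24 (404) and COX5A (265). Proteasome genes had 9 of 24, with Rpn3 (309), Rpn6 (230), Prosalpha4 (199) and Rpn13 (166). The cytochrome P450 list, matched by gene name, had 4 of 20 (exact test, adjusted p = 0.0753): Cyp6u1 (765), Cyp1 (117), Cyp317a1 (113) and Cyp6t1 (94.0). Cyp1 is a cyclophilin gene that the name match let in, so counts and tests of this list include a gene that is not a P450. The P450 list passed, with a lower share, in 5 of 9 other settings, among them the conservative list (exact test, adjusted p = 0.00863).

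The X chromosome held more peaks than the failing candidates would give. It carried 1023 of the 5140 arm peaks (19.9%, 18.83 to 21.02%, or 43.5 per Mb), against 12.9% of 28416 failing candidates (log2 odds ratio 0.75 ± 0.06 SE; two-sided Fisher's exact test, adjusted p = 3.18e-37 over 6 arms). Against arm length, of which the X makes up 17.6%, the log2 odds ratio was 0.22. That excess was lost in the 119 windows of 1 Mb with at least 20 protein-coding genes, where it was 0.04 ± 0.05 SE (exact binomial test, p = 0.397), in a test chosen after seeing the data. The windows left out, poor in genes, were 18 on the autosomes and 1 on the X. The share on 3R was lower (22.6% against 26.4%, exact test, adjusted p = 1.42e-08), and so was that on 2R (17.8% against 19.3%, adjusted p = 0.0207). Shares of the arms sum to a whole, so the higher X share by itself lowers those of the other arms. Neither 3R nor 2R was tested with the X left out, so these calls are not separate from that of the X. On 2R the call was lost without replicate 1 (exact test, adjusted p = 0.307), at an IDR of 0.001 (0.0713) and against arm length (0.0719). Chromosome 4 held 7 peaks, a share no lower than that of failing candidates (0.136% against 0.102%, exact test, adjusted p = 0.486). By length it held few, 5.19 per Mb against 36.2 to 40.1 per Mb on the other autosomal arms.

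Summits were rich in A and T. Windows of 50 bp to either side of passing summits had a mean GC content of 34.5% (SD 9.71, n = 5140 windows), against 46.0% (SD 10.3, n = 28416) at failing summits. The dip was local: 400 bp to either side, passing windows had 43.8% and 43.6%. It was present at promoter summits (35.3%) and at distal ones (33.9%). It followed signal, from 31.7% in the top 1000 peaks to 38.1% at ranks 4001 to 5000. The weakest passing peaks, at ranks 5001 to 5153, had 44.8%, near the value of failing summits. The strong summits in CG11050 (21.8%) and at mRpL23 (19.8%) were among the lowest, and the one near lncRNA:CR45643 reached 46.5%.

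**Figure D3:**
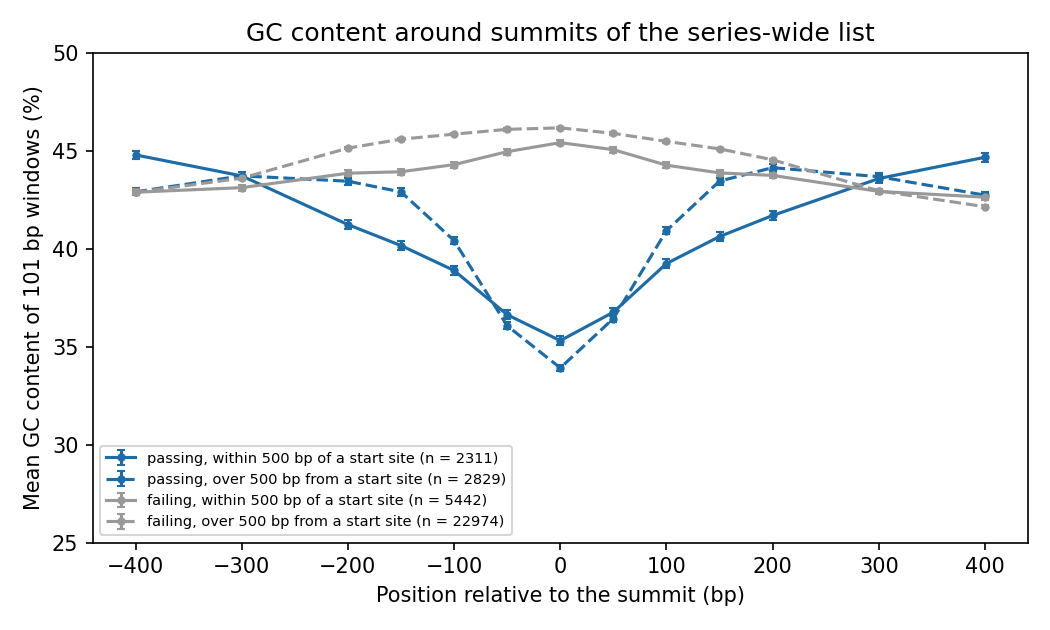
Mean GC content of windows reaching 50 bp to either side (vertical axis, %, beginning at 25) by position relative to the summit (horizontal axis, bp), for passing peaks in blue and failing candidates in grey, near start sites (solid) and away from them (dashed); bars are standard errors over windows. Passing summits dip to 35.3% and 33.9%, and failing summits rise to 45.4% and 46.2%.

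Among 17 known motifs, the CTCF core AGRKGGCGC was the most enriched at GC-matched summits. It was found within 100 bp of 111 of 4904 passing summits (2.26%, 1.88 to 2.72%) and of 45 of 4904 failing ones matched on GC content and promoter position (0.918%; log2 odds ratio 1.31 ± 0.26 SE; two-sided Fisher's exact test, adjusted p = 1.74e-06). Ohler motif 7 followed (7.67% against 5.26%, exact test, adjusted p = 1.24e-05), then the BEAF-32 box CGATA (27.4% against 24.8%, adjusted p = 0.0199), while CA repeats were rarer (3.61% against 4.83%, adjusted p = 0.0170). In the list of replicate 2 alone, Ohler motif 7 (exact test, adjusted p = 0.0518), the BEAF-32 box and the CA repeat (both adjusted p = 0.190) no longer passed, and in that of replicate 1 alone the CA repeat did not (adjusted p = 0.721). The CA repeat call held in only 2 of 7 other settings, being lost also in the conservative list (exact test, adjusted p = 0.271), at an IDR of 0.001 (0.207) and with 200 bp windows (0.869), and the BEAF-32 call was lost also with 50 bp windows (0.0582) and at an IDR of 0.001 (0.207). The other 13 motifs did not pass, among them the GAGA element (3.18% against 2.43%, exact test, adjusted p = 0.0779), the DNA replication-related element TATCGATA (3.24% against 2.69%, adjusted p = 0.237), Motif 1, the E-box (adjusted p = 0.0765), the GATA site and the Zelda site. The GAGA element and the E-box each passed as enriched in 4 of 7 other settings, which were the 200 bp window (exact test, adjusted p = 6.37e-08 and 2.29e-05), the conservative list (0.0303 and 9.90e-06), replicate 1's list (0.0283 and 0.00357) and replicate 2's list (0.00318 and 0.00217). The DNA replication-related element passed in the conservative list (exact test, adjusted p = 3.42e-04) and with 50 bp windows (0.0238), and Motif 1 with 200 bp windows (0.00639) and in replicate 1's list (0.0397). The GATA site passed with 200 bp windows (exact test, adjusted p = 0.00639), and the TATA box passed as rarer in replicate 1's list (0.0348). Against flanks of the same peaks, 400 bp away, the DNA replication-related element was 3.35% against 0.739% (exact test, adjusted p = 1.03e-20) and the GAGA element (3.17% against 5.39%, adjusted p = 7.56e-08) and the E-box (adjusted p = 0.0371) turned lower at summits. In all, 13 of the 17 motifs passed against flanks, among them the GATA site (exact test, adjusted p = 7.41e-15), and flanks are not matched on GC content. Each flank came from the same peak as a summit window, and the exact test did not use that pairing.

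A search over all 8-mers, against failing windows matched on GC content, gave a few rare sequences at summits. Of 20 8-mers chosen on 2L, 2R and X, 6 passed on the held-out arms 3L, 3R and 4. CACCCTGT was found within 50 bp of 38 of 2102 summits (1.81%, 1.32 to 2.47%), against 6 of 2230 matched ones (0.269%; two-sided Fisher's exact test, adjusted p = 3.56e-06), and the overlapping TACAGGGT of 32 (1.52% against 0.314%, adjusted p = 2.97e-04). GGTGGCGC, AGGTGGCG and TAGGTGGC, which overlap each other, were at 0.618%, 0.714% and 0.571% of summits and at no more than 0.0897% of matched ones. GGTGGCGC and AGGTGGCG each fit inside the CTCF core AGRKGGCGC, and TAGGTGGC overlaps its start. These overlapping words may therefore repeat the CTCF call above and are not counted as separate from it. Summits without that core were not tested for them. CCACTGTG stood at 1.62% against 0.448% (exact test, adjusted p = 5.60e-04). No 8-mer in this test reached 2% of the held-out summits. In the list of replicate 2 alone, 2 of 20 passed. Matching on GC content works against words rich in A and T. Against flanks of the same peaks, which are not so matched, all 20 chosen 8-mers passed, in a test that ignored the pairing. More common words were among them. TTTTTAAA, for instance, was at 6.77% of held-out summits and 1.86% of flanks, and ATTTTTAA at 5.80% and 1.28%.

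Small RNA genes were near few peaks. A tRNA, snRNA, snoRNA or rRNA gene lay within 500 bp of 29 of 5153 passing summits (0.563%, 0.392 to 0.807%), against 87 of 28717 failing ones (0.303%; log2 odds ratio 0.91 ± 0.31 SE; two-sided Fisher's exact test, p = 0.00602). By type, tRNA genes were near 13 summits (0.252% against 0.174%, two-sided Fisher's exact test, p = 0.221). For snoRNA genes there were 11 (0.213% against 0.111%, exact test, p = 0.0844). For snRNA genes there were 6 (0.116% against 0.0244%, exact test, p = 0.00807), and for rRNA genes 0. These p-values were not adjusted over types. Start sites of small RNA genes also counted in the promoter test, where passing summits were enriched more (log2 odds ratio 1.80 ± 0.05 SE). Promoter position was not matched here, so a preference for small RNA genes beyond that for promoters was not shown.

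The CG10366 locus itself held passing peaks in every list. The tagged construct was taken to carry the gene, and control libraries were not analysed. Reads from the construct were therefore not told apart from binding at this locus. CG10366 spans 19584235 to 19586440 on the plus strand of 2L. The series-wide list held 3 passing peaks within 5000 bp. One overlapped the start of the gene (19584006 to 19584335, signal 216), with its summit 64 bp upstream of the start site and the sequence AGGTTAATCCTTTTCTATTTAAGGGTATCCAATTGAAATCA. Another lay 863 bp past the gene's end, in the 5' UTR of a neighbour (19587138 to 19587467, signal 223). The remaining one had its summit at -1750 bp from the start site (19582320 to 19582649, signal 113). The first and second of these places also held passing peaks in replicate 1 and in replicate 2, while the upstream one failed in replicate 2. The conservative list added a peak in an intron of a neighbour (19591106 to 19591435, signal 67.8). By signal these peaks ranked 1397 to 3362 of the 5153, so the tagged gene's own locus was not among the strongest sites.

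**Figure D4:**
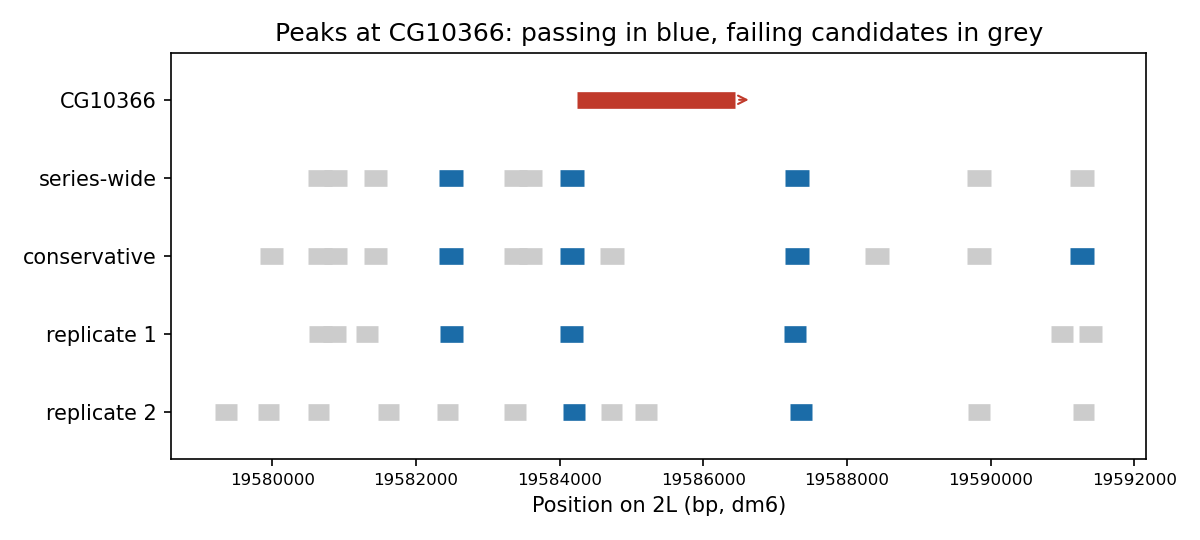
Peaks within 5000 bp of CG10366 on 2L (horizontal axis, bp in dm6), 1 row for each list; blue bars are passing peaks, grey bars failing candidates and the red bar the gene, with an arrow for its direction. The peak over the gene's start and the one past its end are present in all 4 lists.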

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

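The tests by arm and by start site were chosen after these regions had been seen, and the tests of the explanations were written down after the pattern was seen, just before their values were computed. Strong regions outside the passing list drew attention because they hold signal in data that the comparisons do not use: 148 regions met the authors' IDR threshold and are not in the series-wide list. Their median signal was 126, against 142 for passing peaks, and 2 would have ranked among the top 10. These were an intron of ush on 2L (480921 to 481256, signal 2897) and an intron of Lk6 on 3R (11760893 to 11761212, signal 2281), followed by larp (1318), lncRNA:CR30055 (1273), trx (1118) and CG18428 (1064). They gathered on 3R, with 78 of 148 (52.7% against 22.5% of passing peaks, two-sided Fisher's exact test, adjusted p = 2.58e-14). Many stood close together in the same gene, as at Kdm2, tara, CG8312, InR and trx on 3R. The regions are thus not independent, and the test by arm overstates the evidence. At start sites they were placed much as passing peaks were, with 42.6% within 500 bp against 44.8% (two-sided Fisher's exact test, p = 0.615).

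A candidate explanation is repeated sequence that draws reads from many places. Among left-out regions on the arms, the soft-masked share was 19.6%, and that of passing peaks nearest in signal 19.99%. The difference of -0.41 percentage points (SE 1.51) gave no sign of more repeats there. Left-out regions on unplaced and Y scaffolds were not in this comparison, which leaves repeats open for them. The rule written beforehand counted any difference within 2 SE of 0 against repeats; it was set too loosely, since with this SE a small excess would have met it too, and that stays open. Small RNA genes were another: 1 of 148 lay within 500 bp of one (0.676% against 0.563%, Fisher's exact test, p = 0.573). That is too few to tell whether the share differed. All but 1 had no annotated small RNA gene that near, which argues against such genes as the cause for most of the regions. Regions on scaffolds without annotated genes could not be judged. The authors' filter itself, for instance on signal in control libraries, stays open as untested, and no biological explanation was tested.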

How the results depend on the processing

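The IDR of 0.001, GC-matched promoter background, left-out regions added back, genes or pairs counted once or 1 gene drawn of each pair, and 8-mers per replicate were chosen after seeing the data. The planned IDR of 0.01 was the authors' own threshold and so changed nothing; it is not counted. Of 387 values under alternatives, 309 kept their call, though many that passed in neither setting changed sign. The promoter share (log2 odds ratio 1.53 to 2.37), divergent promoters (1.56 to 2.38, the highest with any gene of a pair counted, which raises it by construction), small RNA genes (0.78 to 1.17), cytoplasmic ribosomal proteins (2.37 to 3.28), the CTCF core (1.16 to 2.61) and replicate overlap (71.7 to 90.8%) kept direction and call under each one. The X did so against other lists and arm length (0.22 to 0.72), but not against the length of windows with genes. The causes of the changes below were not tested. Without one replicate, peaks numbered 3378 to 4876, lists past the threshold 2 to 8 (5 in the main), motifs 3 to 7 (4) and 8-mers 2 to 7 (6). Rank concordance was 0.360 over the ranked list. Lists past the threshold were 2 with 250 bp, 9 against all genes and 3 with genes sharing a summit counted once; motifs were 7 with 200 bp windows, 13 against flanks and 2 at the IDR of 0.001; 8-mers were 20 against flanks and 3 as 6-mers. Log2 odds ratios that missed the threshold were, for mitochondrial ribosomal proteins, 0.86 (250 bp), 0.71 (1000 bp), 0.65 (conservative list), 0.95 (IDR of 0.001) and 0.16 without replicate 1, while 1.36 without replicate 2 passed. For neuronal genes they were -1.82 (1000 bp), -1.52 (all genes), -2.04 (counted once) and -2.16 without replicate 1, while -1.91 without replicate 2 passed. For epidermis and cuticle genes they were -3.84 (250 bp), -2.52 (1000 bp), -3.75 (counted once) and -3.45 without replicate 1, while -4.08 without replicate 2 passed. Receptor genes missed it with -3.66 at 250 bp. The CA repeat missed it with -0.031 (200 bp), -0.21 (conservative list), -0.33 (IDR of 0.001) and -0.34 to -0.081 without one replicate or the other. The BEAF-32 box missed it with 0.20 (50 bp), 0.14 (IDR of 0.001) and 0.14 without replicate 1, while 0.16 without replicate 2 passed. Ohler motif 7 missed it with 0.36 without replicate 1, while 0.81 without replicate 2 passed. 2R missed it with -0.10 against length, -0.14 at the IDR of 0.001 and -0.097 without replicate 1. Values that turned direction and passed were chromosome 4 against length (-2.90), and, against flanks, the GAGA element (-0.80), the E-box (-0.22) and the TATA box (0.90). No paired analysis of samples was possible because there is 1 group. The flank comparisons were tested unpaired, although each flank belongs to the same peak as a summit window.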

Other observations

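The listing of genes by number of summits, which are named after their values were seen, the X share by distance from start sites, the 1 Mb windows with each of their limits and the use of arm length as a test of the X excess were chosen after the result was seen. The other tests were written down after the pattern was seen, just before their values were computed. Some genes held many summits. The gene kirre, which encodes a cell adhesion protein of myoblast fusion, held 23 within its 394 kb on X (2740384 to 3134532). CG1677 held 20, sbb on 2R 15, and CHES-1-like, Tlk and ush 12 each. Gene lengths differed widely: per 100 kb, kirre held 5.84 summits, and CHES-1-like, which is 27.0 kb long, held 44.4. Of the 11 genes with at least 10 summits, 7 were on X. The densest 1 Mb window was on 3L (3000001 to 4000000, 85 summits), and 3 of the 10 densest were on X. The X windows 2000001 to 3000000 and 6000001 to 7000000, with 64 summits each, tied with the last of those 10. The median window had 44 summits on X and 42 on the autosomes.

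The excess of X peaks over failing candidates was weighed against a shortage of failing candidates on X. Failing candidates on X lay below its share of arm length (12.9% against 17.6%, log2 odds ratio -0.53 ± 0.03 SE). Passing peaks lay above it (0.22 ± 0.05 SE), but arm length counts stretches poor in genes and peaks that lie mostly on the autosomes. In windows of 1 Mb with at least 20, 40 or 60 protein-coding genes the passing peaks gave 0.043, 0.024 and 0.053, each within 2 SE of 0, and failing candidates -0.69, -0.71 and -0.65. With under 30% of soft-masked sequence passing peaks gave 0.033, but with under 40% or 50% they gave 0.16 and 0.21, each by more than 2 SE, so the answer hung on the reference and a shortage of failing candidates stays open as the whole cause. Leaving out the 5 densest windows gave 0.20 when taken from each large arm and -0.033 when taken from the X alone, and neither decides, since the windows poor in genes stay in. X and autosomal protein-coding promoters had a summit in 19.4% and 19.5% of cases. Within bins of promoter GC content the log2 odds ratio was 0.021 ± 0.09 SE. By the rule first written this would have counted for GC content as the cause, and the rule was changed after the value was seen, because the difference before binning was within 2 SE of 0 (-0.012 ± 0.08 SE). The GC content of promoters was thus not judged. The X share was 22.1% among peaks over 500 bp from a start site and 17.2% among promoter peaks (two-sided Fisher's exact test, p = 9.55e-06), and no biological explanation was tested.

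The A and T richness of summits was weighed against 2 technical readings, with both tests written down as said above. Promoter position was not the cause, since away from start sites passing windows were lower in GC content than failing ones by a difference of -12.3 percentage points (SE 0.18). A library-wide preference for A and T over the scale of fragments would lower the flanks as well, but 400 bp from the summit passing windows lay above failing ones by 1.12 percentage points (SE 0.11). A preference acting over shorter stretches, and the choice of failing candidates, which are themselves rich in G and C, stay open, and no biological explanation was tested.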
